A study of Canis lupus familiaris with 6 samples.

How the data were processed

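RNA from the canine melanoma line CMM10 was sequenced in 3 hypoxia and 3 normoxia libraries. Per the labels' protocols, polyadenylated RNA was selected with oligo-dT beads, libraries were prepared with the NEBNext Ultra II RNA kit, and they were sequenced paired-end on an Illumina NextSeq. This kit does not mark the strand, so reads of a gene cannot be told apart from those of an overlapping or antisense gene. Of the 57 genes named by the rule below, 12 overlap another annotated gene on either strand, among them RSAD2, TAF9B, PLOD2, NDUFS3, MT-ND2, MT-ND1, TM7SF2, SLC7A11, PLK1, KRT14 and ARNT. Their values may hold reads of the other gene. Genes given as further examples can overlap too: the model of CDC6 overlaps that of TOP2A, and the model of FADS1 that of FADS2. Groups came from the treatment label and replicate numbers from the sample titles, and the labels state no oxygen level, no time and no relation between equal replicate numbers.

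Each library came as 1 file with a row for each of 29822 genes of the CanFam3.1 build, named in the submitters' processing notes. The aligner, the counting tool and their versions are not given in the sources used here. Per the file headers, the deposited counts are reads per gene, split into exon, exon-exon and intron reads, each as total and as uniquely mapped reads. Exon and intron reads sum to gene reads, and no source used here states whether a read or a read pair counts as 1. The deposited TPM values, per the file headers, are the expression values, and they have the same sum in each library. The deposited RPKM values, per the file headers a separate column, equal total exon reads over exon length and over a constant per library that is larger than its gene reads, and were not used for any test. A symbol was given for 17892 genes, and 11930 carried only an identifier, of which 2932 were among the tested genes. These unnamed genes stayed in the tests and counts. The reference gene table at hand is of another assembly with no shared identifiers, and was not used here. No genome was used, so GC content was not examined.

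The main test took total gene reads as deposited. Genes were kept by edgeR's filterByExpr by group, leaving 15397, libraries were scaled by TMM, and hypoxia was compared with normoxia by edgeR's quasi-likelihood test (glmQLFit and glmQLFTest with robust estimation) without covariates. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. CPM values used the TMM-scaled library sizes. The common biological coefficient of variation was 4.76%. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (1.17.8), with figures by matplotlib 3.10.9 under Python 3.11.15. Library totals of 23196647 to 28804337 gene reads limit precision mainly for low genes, and unique reads were 93.8% to 94.6% of the total. Library measures were compared by two-sided exact permutation tests, for which 3 against 3 cannot give a p under 0.1.

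The 21 gene lists were fixed from textbook knowledge before the data were examined, as were the tests, the alternatives and the rule for named genes. The lists hold 477 entries, of which 405 were measured, 59 had no matching symbol and 13 were below the count filter, with HK2 and VLDLR each in a pair of lists. Lists were tested by camera with a preset correlation of 0.01, adjusted over the 21 lists by the Benjamini-Hochberg method, and 16 were called, 9 up and 7 down. With the correlation estimated from the data, 3 lists were called: glycolysis, HIF targets and collagen modification. The settings differ in more than the correlation. For the unfolded protein list the estimated correlation (-0.000793) was below the preset 0.01, yet camera p before adjustment rose from 7.24e-04 to 0.0211. A call lost under the estimated setting is therefore not by itself a sign of correlated genes. The rule named the 6 largest rises and 6 largest falls by log2 fold change among called genes with a symbol, a mean of at least 1 CPM and no overlap between the conditions. It also named the 2 called members of each list with the largest absolute change and a mean of at least 1 CPM, or, for a list with none, its member of highest level. SLC2A1, CA9, VEGFA, HIF1A, EPAS1 and ARNT were named in any case. Some genes that the rule takes are not reported here. Further list members given as examples were chosen after their values were seen.

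Counts were simulated with the normoxia levels and the library sizes of the data (14972 genes run for the comparison of hypoxia with normoxia). Of 50 genes changed at each size, the test recovered 76% at 1.25-fold, 76% at 1.5-fold, 92% at 2-fold and 92% at 4-fold. Changed genes that the filter removed counted as not recovered. Unchanged genes were 8.20% of the test's calls. Far fewer genes were changed here than were called in the real data, so these shares need not hold there. In simulated lists for the same comparison (14964 genes run), a list raised by 1.5-fold was called up and an unchanged list had a camera p of 0.300. Genes were simulated independently of each other, so this does not show how camera treats lists of correlated genes. Exon and intron changes were compared by an interaction term in one edgeR model over exon and uniquely mapped intron counts of genes with at least 60 of each over all libraries. On simulated counts of 11568 genes for that comparison, 64% of genes changed by 1.5-fold and 81% by 2-fold were recovered, and 8.23% of calls were unchanged genes.

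Alternatives were RLE, upper quartile and no scaling factors, DESeq2, limma-voom, no low-count filter, a filter of 1 CPM in 3 libraries, a null of a 1.5-fold change (glmTreat), uniquely mapped reads, and limma on the deposited TPM as log2(TPM + 1) or log2(TPM + 0.1). Further ones were the replicate number as a block, removal of a gene length trend, both together, and each library left out in turn. For lists, an estimated correlation, fry, the block, library size only, the CPM filter and each library left out were tried. Counts from exon reads only and counts thinned to the smallest library were added after the data had been seen. The TPM alternatives give changes on the log2(TPM + pseudocount) scale, which understates the change of low genes.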

Results

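Transcript levels were measured by RNA sequencing in CMM10, a canine malignant melanoma cell line, kept under hypoxia or under normoxia. Each condition was represented by 3 libraries, and the labels give neither the oxygen level nor the time under hypoxia. The reads assigned to genes numbered 28804337, 28482908 and 27272709 in hypoxia replicates 1, 2 and 3, and 25946261, 27012866 and 23196647 in normoxia replicates 1, 2 and 3. The hypoxia libraries were thus deeper (28186700 ± 807649 against 25385258 ± 1968990 reads, mean ± SD, n = 3 per group, two-sided exact permutation p = 0.1, the smallest p that 3 against 3 can give). Reads in introns made up 24.6% ± 0.67 of gene reads under hypoxia and 24.2% ± 0.77 under normoxia (n = 3 per group, exact permutation p = 0.6). The labels list the libraries as separate samples, and each was counted as one. Replicates differed from each other by more than the sampling noise of independent reads, with a chi-square per degree of freedom of 4.29 to 13.7. The median over genes was lower, at 2.63 to 3.33 times its expected value. If both reads of a pair were counted, which is not known, that alone would raise these values. They do not show that the replicates were separate cultures. The log2 CPM of replicates correlated across genes with r of at least 0.996, genes not being independent replicates. The first principal component held 62.0% of the variance and separated the conditions, and the second held 11.3%.

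The comparison of hypoxia with normoxia addressed which genes, metabolic genes above all, change their expression in these tumour cells when oxygen is low. Genes of glycolysis and other known targets of the hypoxia-inducible factors (HIF) rose most, with median changes of 4.14-fold and 3.88-fold. Smaller falls were found in 34 of 44 nuclear-encoded and 11 of 13 mitochondrially encoded respiratory chain genes, 18 of 21 genes of ribosome biogenesis and MYC and 23 of 23 mitotic genes. As lists, these were called down by camera with a preset correlation, but not with an estimated one (adjusted p = 0.274, 0.104, 0.0898 and 0.0727). Carbonic anhydrase 9 (CA9), which regulates pH at the cell surface, reached 408.8 ± 4.84 CPM under hypoxia against 29.9 ± 1.00 CPM under normoxia, a 13.7-fold difference. The glucose transporter SLC2A1 reached 624.7 ± 17.5 against 111.0 ± 4.86 CPM (5.63-fold), and the angiogenic factor VEGFA 723.5 ± 39.3 against 207.3 ± 8.38 CPM (3.49-fold). CA9 lies on chromosome 11 (52205668 to 52211267), SLC2A1 on chromosome 15 (463237 to 493140) and VEGFA on chromosome 12 (12208231 to 12224965) of CanFam3.1. Here and below, levels are mean CPM ± SD of 3 libraries per group, and changes are log2 fold changes ± SE of hypoxia over normoxia.

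Of 15397 genes tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, 3778 were higher and 3761 lower under hypoxia. Rises were larger than falls: 740 genes rose and 74 fell by over 2-fold, and 171 rose and 5 fell by over 4-fold. Against a null of a 1.5-fold change, 756 genes were higher and 95 lower. With library size as the only scaling, the split was 3076 higher and 4862 lower, or 38.8% higher among calls against 50.1% with TMM factors. The hypoxia and normoxia values did not overlap in 8508 genes, or 55.3% of those tested, where chance gives 10%. The p-values judge the difference between conditions against the spread within each group. The labels do not say that the replicates were separate cultures, so that spread may be technical.

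**Figure D1:**
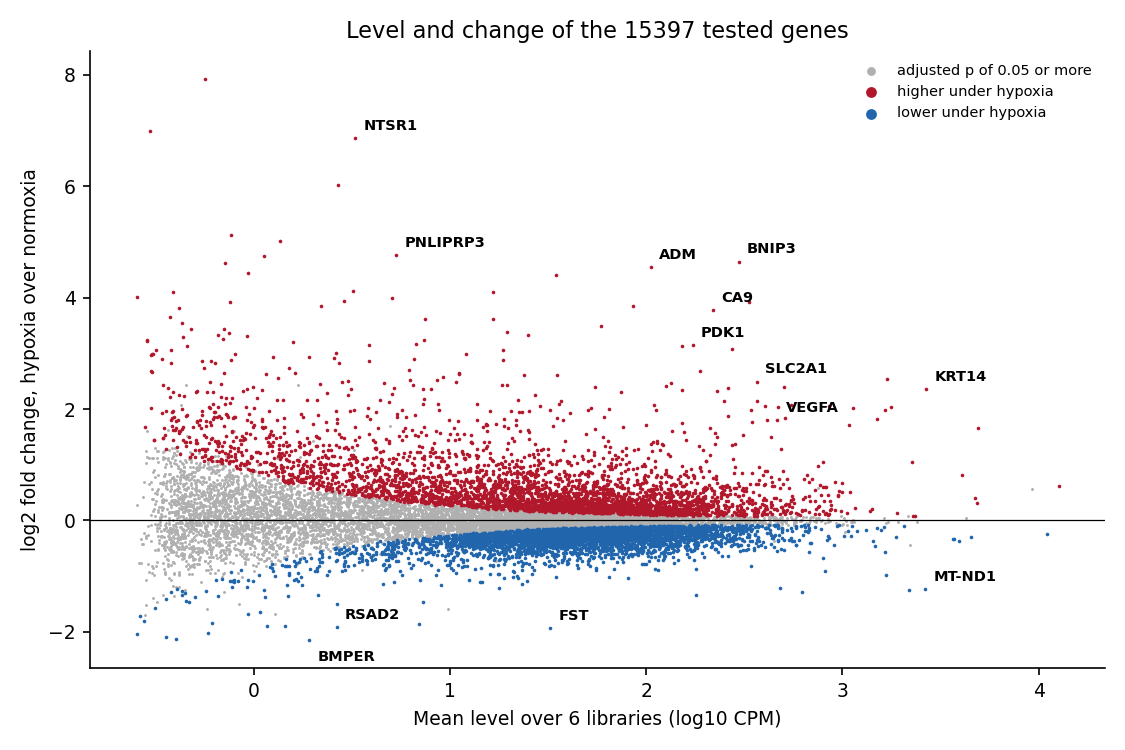
Mean level over the 6 libraries (log10 CPM) against the log2 fold change of hypoxia over normoxia for each of the 15397 tested genes, coloured by direction at an adjusted p of 0.05. Rises extend further than falls, up to a log2 change of 7.93 against -2.15.

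Among genes with a symbol and a mean of at least 1 CPM, the neurotensin receptor NTSR1 had the largest rise, from 0.049 ± 0.043 to 6.54 ± 0.42 CPM (6.87 ± 0.35). This rested on 4 normoxia reads in all, against 541 under hypoxia. FAM71F2 (5.02 ± 0.47), the pancreatic lipase family member PNLIPRP3 (4.77 ± 0.22) and KIRREL2 (4.75 ± 0.47) also rose from low levels, with 6, 29 and 6 normoxia reads. The mitophagy receptor BNIP3 rose from 22.8 ± 4.39 to 569.8 ± 10.2 CPM (4.64 ± 0.13) and the vasodilator peptide adrenomedullin, ADM, from 8.62 ± 1.24 to 202.2 ± 5.56 CPM (4.55 ± 0.063). The 6 largest falls were smaller. BMPER, a regulator of BMP signalling, fell by 2.15 (from 3.13 ± 0.19 to 0.70 ± 0.080 CPM), and follistatin, FST, which binds activin, fell by 1.94 (from 51.6 ± 2.82 to 13.5 ± 0.55 CPM). RSAD2 (-1.92 ± 0.25), PCP4 (-1.90 ± 0.30), SYPL2 (-1.89 ± 0.36) and TAF9B (-1.86 ± 0.14) followed. The largest adjusted p among these 12 genes was that of SYPL2 (4.51e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The main test counts intron reads, which were 57.3% of the reads of FAM71F2, 48.9% for SYPL2 and 48.8% for BMPER. The next highest share among the 12 was 25.7%, for PNLIPRP3.

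In the list of glycolysis and glucose uptake, 16 of 18 measured genes rose and 0 fell, with a median log2 change of 2.05. The pyruvate dehydrogenase kinase PDK1, which holds back pyruvate entry into the TCA cycle, rose from 34.98 ± 4.68 to 310.2 ± 15.8 CPM (3.15 ± 0.094). The aldolase ALDOC rose from 31.2 ± 2.42 to 274.2 ± 10.4 CPM (3.14 ± 0.049), and the transporter SLC2A3 by 3.08 and hexokinase HK2 by 2.46. PFKM (-0.02) and PFKFB4 (-0.03) did not pass the test, while ALDOA, PGAM1, PKM and LDHA were matched to no symbol and were not analysed here. Of 33 measured genes in the list of HIF targets outside glycolysis, which also holds HK2, 31 rose and 0 fell, with a median of 1.96. The prolyl hydroxylase EGLN3, which marks HIF for degradation, rose by 3.50, the mTORC1 inhibitor DDIT4 by 3.93 and NDUFA4L2 by 4.11. PLIN2 (0.08) and RASSF1 (-0.07) did not pass the test. Adjusted over the list alone, both lists gave the same counts, 16 and 31 genes higher. Both stood above other genes in camera with a preset correlation (adjusted p = 3.92e-147 and 7.55e-170) and with an estimated correlation (adjusted p = 0.00288 and 7.56e-04).

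**Figure D2:**
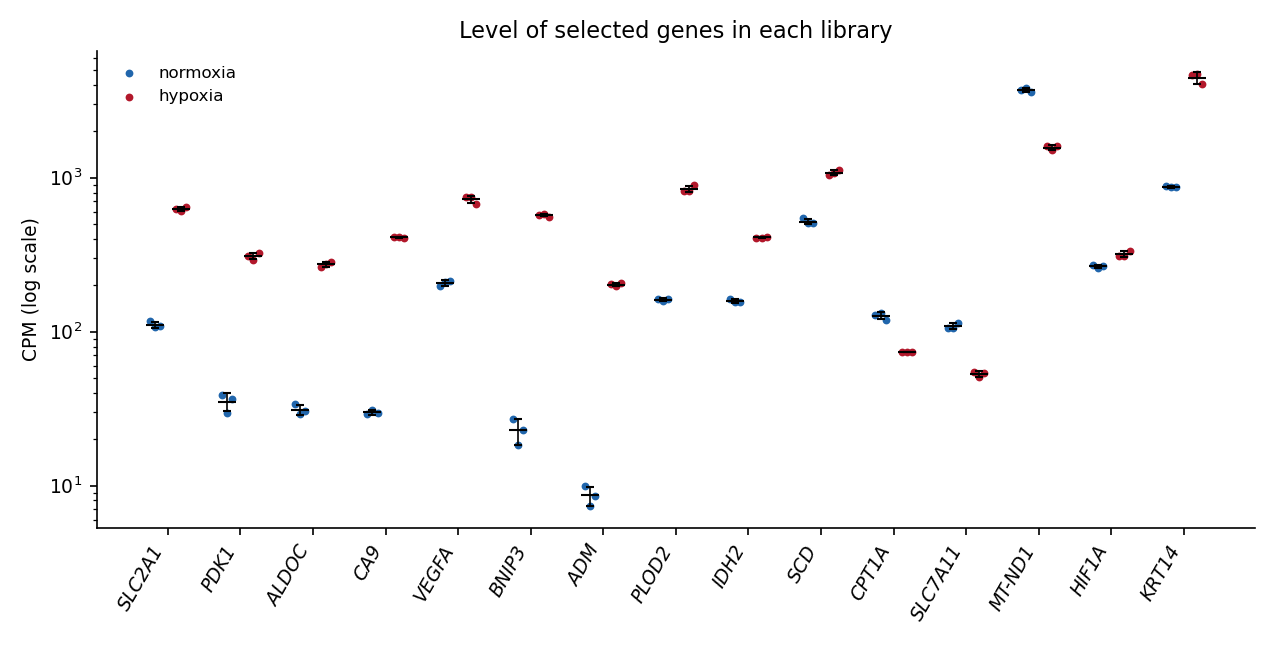
CPM on a log scale of 15 genes in each normoxia (blue) and hypoxia (red) library, with horizontal bars for the mean and error bars for the SD of 3 libraries. CA9 averages 408.8 CPM under hypoxia and 29.9 CPM under normoxia, whereas SLC7A11 averages 53.1 and 108.4 CPM.

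Of the HIF subunits, EPAS1 (HIF-2α) was higher under hypoxia, at 17.1 ± 1.17 against 10.3 ± 0.53 CPM (0.73 ± 0.096, adjusted p = 1.15e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Gene reads of HIF1A, on chromosome 8 from 36614045 to 36656692, were 318.3 ± 13.1 against 264.9 ± 5.54 CPM (0.26 ± 0.036, adjusted p = 2.08e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). That difference lay in intron reads: from exon reads only, HIF1A changed by 0.04 ± 0.037 and did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.351). ARNT, the shared partner subunit, was at 70.9 ± 3.96 against 65.9 ± 2.16 CPM (0.11 ± 0.051) and did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.0851). It passed when hypoxia replicate 1 was left out (0.15, adjusted p = 0.0254 by edgeR with Benjamini-Hochberg adjustment) and from exon reads only (0.16, adjusted p = 0.0153 by edgeR with Benjamini-Hochberg adjustment).

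In glycogen metabolism, 8 of 14 genes rose and 3 fell, with a median of 0.36, and the counts adjusted over the list alone were also 8 and 3. Glycogen synthase GYS1 rose from 20.7 ± 1.80 to 83.6 ± 2.67 CPM (2.01 ± 0.061) and PPP1R3C, which targets protein phosphatase 1 to glycogen, by 1.88 ± 0.20. GYG1 (-0.15), PHKB (-0.10) and PYGB (-0.08) fell slightly. The list was called up by camera (adjusted p = 2.16e-04), but not with an estimated correlation (adjusted p = 0.101). In the list of collagen modification and extracellular matrix, 15 of 20 genes rose and 2 fell, also when adjusted over the list alone, with a median of 0.52. The collagen lysyl hydroxylase PLOD2 rose from 161.0 ± 3.15 to 847.1 ± 41.2 CPM (2.40 ± 0.038) and the prolyl hydroxylase subunit P4HA1 from 135.4 ± 6.15 to 599.5 ± 27.6 CPM (2.15 ± 0.040). LOXL1 (-0.21) and SERPINH1 (-0.11) fell. Camera called this list up (adjusted p = 9.42e-23), with an estimated correlation too (adjusted p = 0.0165).

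Of 17 TCA cycle genes, 11 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.24. The gene that rose was IDH2, the NADP-dependent mitochondrial isocitrate dehydrogenase, from 158.2 ± 4.03 to 409.6 ± 3.8 CPM (1.37 ± 0.035), while IDH3A, of the NAD-dependent enzyme, fell by 0.45. The list as a whole was not called by camera (adjusted p = 0.0829). It passed with library size as the only scaling (adjusted p = 0.0312 by camera) and without normoxia replicate 3 (adjusted p = 0.0441 by camera). Of 44 nuclear-encoded respiratory chain genes, 34 fell and 0 rose, adjusted over the list alone too. The median was -0.19, and CYC1 (-0.47 ± 0.047) and NDUFS3 (-0.46 ± 0.053) fell most. Camera called the list down (adjusted p = 2.33e-05), though not with an estimated correlation (adjusted p = 0.274).

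Of the 13 mRNAs encoded on the mitochondrial genome, 11 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.34. MT-ND2, at positions 3914 to 4957, fell from 3071 ± 33.7 to 1290 ± 45.1 CPM (-1.25 ± 0.033), and MT-ND1, at 2747 to 3703, from 3711 ± 129.0 to 1569 ± 55.2 CPM (-1.24 ± 0.035). MT-CYB fell by 0.99, and the other 10 mRNAs had changes between -0.41 and 0.00. The list was called down by camera (adjusted p = 1.07e-10), but not with an estimated correlation (adjusted p = 0.104). Mitochondrial reads made up 3.27% ± 0.060 of gene reads under hypoxia and 4.56% ± 0.054 under normoxia (n = 3 per group, exact permutation p = 0.1, the smallest possible).

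**Figure D3:**
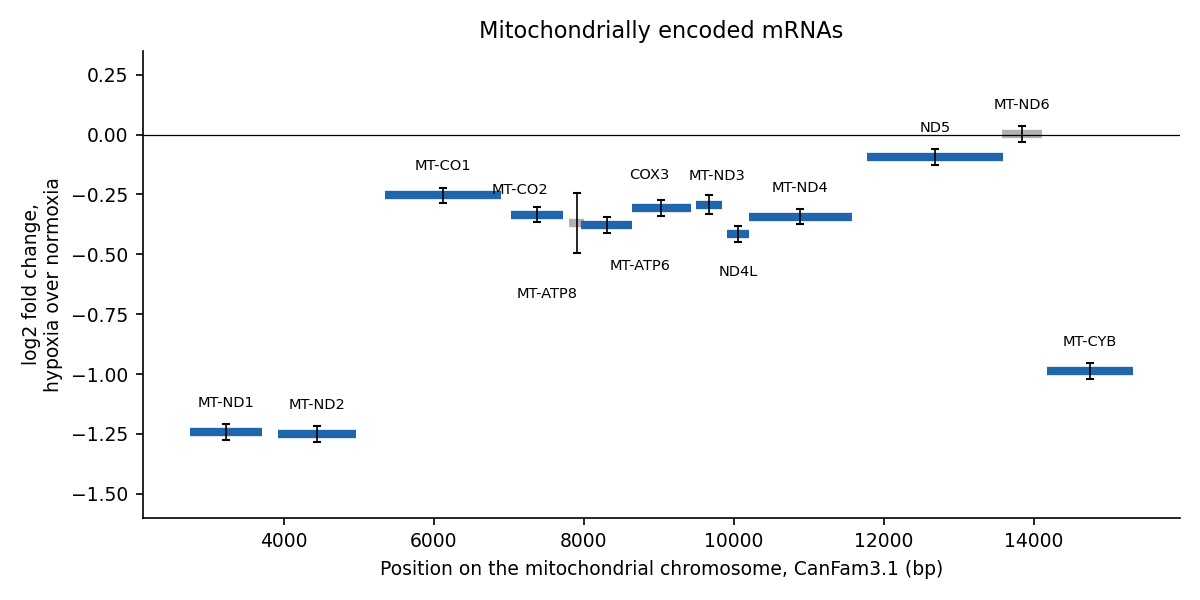
Log2 fold change of hypoxia over normoxia (± SE) of each mitochondrially encoded mRNA, drawn at its position in bp on the mitochondrial chromosome, in blue where adjusted p was below 0.05 and in grey otherwise. MT-ND1, MT-ND2 and MT-CYB lie at -1.24, -1.25 and -0.99, and the other 10 between -0.41 and 0.00.

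Among lipid genes, 17 of 22 genes of cholesterol synthesis and uptake rose and 1, MVK, fell (-0.22), with the same counts adjusted over the list alone and a median of 0.39. The sterol reductase TM7SF2 rose from 45.0 ± 2.18 to 99.4 ± 1.37 CPM (1.14 ± 0.049). The list was called up by camera (adjusted p = 1.32e-09), though not with an estimated correlation (adjusted p = 0.0727). Of 19 genes of fatty acid synthesis and storage, 8 rose and 7 fell (8 and 8 adjusted over the list alone), with a median of 0.08. LPIN1 (1.33 ± 0.040, with 43.9% of its reads in introns) and the stearoyl-CoA desaturase SCD (1.06 ± 0.035) rose, whereas DGAT2 (-0.40) and FADS1 (-0.31) fell. This mixed list was called up by camera (adjusted p = 0.00375), but not with an estimated correlation (adjusted p = 0.157). In fatty acid oxidation, 6 of 16 genes fell and 2 rose (6 and 3 adjusted over the list alone), with a median of -0.07. CPT1A, which admits fatty acids to mitochondria, fell from 126.6 ± 6.56 to 73.9 ± 0.085 CPM (-0.78 ± 0.044), and SLC25A20, the carnitine carrier, by 0.65. The list was not called by camera (adjusted p = 0.0829) but passed with library size as the only scaling (adjusted p = 0.0454 by camera) and without normoxia replicate 3 (adjusted p = 0.0468 by camera).

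In serine, one-carbon and amino acid metabolism, 8 of 21 genes rose and 7 fell, adjusted over the list alone too. The median was 0.03 and the mean -0.04, and camera gave no call (direction down, adjusted p = 0.462). The cystine transporter SLC7A11 fell from 108.4 ± 4.79 to 53.1 ± 2.25 CPM (-1.03 ± 0.048), with 86.5% of its reads in introns, and mitochondrial serine hydroxymethyltransferase SHMT2 rose from 349.6 ± 11 to 646.4 ± 10.3 CPM (0.89 ± 0.034). Of 6 measured pentose phosphate genes 3 fell and 0 rose, adjusted over the list alone too, with a median of -0.21. PRPS1 (-0.61 ± 0.044, with 42.2% of its reads in introns) and PRPS2 (-0.37), which make phosphoribosyl pyrophosphate, were among those that fell. Camera called the list down (adjusted p = 0.0153), but not with an estimated correlation (adjusted p = 0.274) or from exon reads only (adjusted p = 0.0520).

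All 23 measured genes of G2 and mitosis fell, adjusted over the list alone too, with a median of -0.32. They included the mitotic kinase PLK1 (-0.59 ± 0.042) and CDC20 (-0.57 ± 0.042), an activator of the anaphase-promoting complex. Camera called the list down (adjusted p = 1.32e-09), though not with an estimated correlation (adjusted p = 0.0727). Of 26 DNA replication genes, 20 fell and 2, CDT1 (0.29) and CDC6 (0.25), rose, adjusted over the list alone too. The median was -0.24, with RFC3 (-0.48 ± 0.063) and MCM4 (-0.46 ± 0.035) lowest. The CDC6 model overlaps that of TOP2A, so the CDC6 value may hold TOP2A reads. This list was also called down by camera (adjusted p = 1.88e-04), but not with an estimated correlation (adjusted p = 0.181). In the list of ribosome biogenesis and MYC, 18 of 21 genes fell and 2 rose, adjusted over the list alone too, with a median of -0.48. WDR12, needed for the large ribosomal subunit, fell from 33.6 ± 1.13 to 18.8 ± 1.47 CPM (-0.84 ± 0.072). The transferrin receptor TFRC, which imports iron, rose from 129.9 ± 5.40 to 272.2 ± 5.84 CPM (1.07 ± 0.038), RRP12 also rose (0.58), and MYC did not pass the test (-0.08). The list was called down by camera (adjusted p = 1.32e-09), but not with an estimated correlation (adjusted p = 0.0898).

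Stress and signalling genes showed mixed directions. In the unfolded protein and integrated stress response, 11 of 20 genes rose and 2 fell, adjusted over the list alone too, with a median of 0.28. VLDLR, a lipoprotein receptor that is also in the HIF list, rose by 2.09 ± 0.10 and CHAC1, which degrades glutathione, by 1.12 ± 0.16, while the ER chaperones HYOU1 (-0.19) and PDIA4 (-0.15) fell. Camera called the list up (adjusted p = 0.00127), but not with an estimated correlation (adjusted p = 0.0727). Of 13 interferon response genes, 8 fell and 0 rose, adjusted over the list alone too, with a median of -0.26. RSAD2 (-1.92 ± 0.25) and IFI44 (-0.87 ± 0.11) fell most. In camera the list was called down (adjusted p = 0.0229), but not with an estimated correlation (adjusted p = 0.264). Of 15 immediate early and heat shock genes, 9 rose and 4 fell, adjusted over the list alone too, with a median of 0.34. FOSB, a subunit of AP-1, rose from 1.68 ± 0.36 to 8.70 ± 0.61 CPM (2.38 ± 0.17) and DUSP1, a phosphatase of MAP kinases, by 1.22 ± 0.12, whereas the chaperones HSPH1 (-0.66) and HSPA8 (-0.58) fell. The list was not called by camera (adjusted p = 0.108).

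Melanocyte genes moved in both directions. Of 15 measured genes 3 rose and 4 fell, adjusted over the list alone too. The median was 0.08 and the mean -0.02, and camera gave no call (direction down, adjusted p = 0.825). SLC45A2, a melanosomal transporter, rose from 65.9 ± 2.91 to 91.7 ± 4.34 CPM (0.48 ± 0.049) and MCOLN3, a lysosomal channel, fell by 0.45. Introns held 38.0% of the reads of SLC45A2 and 41.1% of those of MCOLN3. TYR, TYRP1 and TRPM1 were below the count filter. Of 18 mesenchymal and invasion genes, 14 rose and 3 fell, adjusted over the list alone too, with a median of 0.32. The fibronectin receptor subunit ITGA5 rose from 49.5 ± 2.88 to 77.4 ± 0.89 CPM (0.64 ± 0.051), and ZEB1 fell (-0.39). The epithelial cadherin CDH1 (0.47) is a member of this list and 1 of its 14 rises. NGFR fell from 2.66 ± 0.24 to 1.65 ± 0.36 CPM (-0.69 ± 0.24, adjusted p = 0.0156 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its call was lost without hypoxia replicate 1 (adjusted p = 0.0767, edgeR with Benjamini-Hochberg adjustment) and without normoxia replicate 1 (adjusted p = 0.0628, edgeR with Benjamini-Hochberg adjustment). Camera called the mesenchymal list up (adjusted p = 6.93e-04), but not with an estimated correlation (adjusted p = 0.0727).

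Of 20 markers of other cell types, 11 were measured, 6 were below the count filter and 3 had no matching symbol. Of the measured markers 3 rose and 1 fell, adjusted over the list alone too, with a median of 0.40. The basal keratin KRT14, on chromosome 9 from 21156045 to 21265564, rose from 873.5 ± 12.2 to 4456 ± 369 CPM (2.35 ± 0.050). Its annotated model contains another keratin gene, KRT9, and reads of overlapping genes cannot be separated by strand with this library kit. PDGFRA rose from 1.52 ± 0.33 to 6.12 ± 0.50 CPM (2.01 ± 0.19), VWF rose by 1.44, and EPCAM fell by 0.15. In camera the list was called up (adjusted p = 0.00500), but not with an estimated correlation (adjusted p = 0.121).

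**Figure D4:**
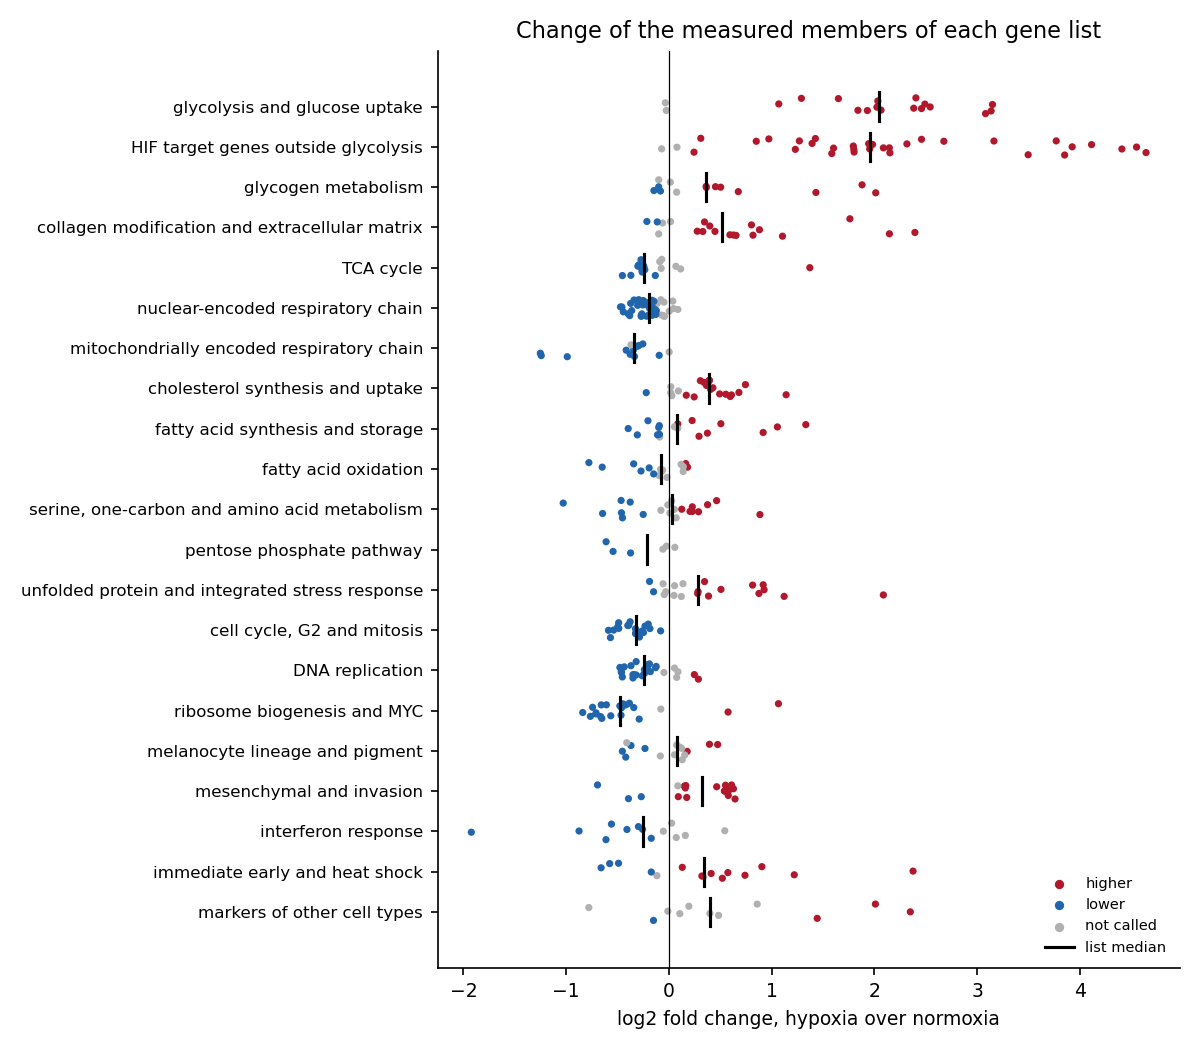
Log2 fold change of hypoxia over normoxia of each measured gene (points) in the 21 gene lists, in red or blue where higher or lower at an adjusted p of 0.05 and in grey otherwise, with the list median as a black bar. The glycolysis and HIF target lists have medians of 2.05 and 1.96, while the medians of all other lists lie between -0.48 and 0.52.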

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

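Of the tests in this part, the overlap of genes called in the exon and intron comparison with other genes, the look inside the KRT14 model and the splits were fixed before their results were seen, while those on HIF1A, on the mitochondrial mRNAs, on epithelial genes and on multiply mapped reads were chosen afterwards.

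The counts of called genes and lists were set against other groupings of the libraries. With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. In 1 of the 10 splits, the real one, edgeR called 3778 genes higher and 3761 lower. The highest other split called 0 in one direction. Each other split puts both conditions in both groups, so a hypoxia effect widens the spread within groups. Few gene calls there were thus fixed in advance, and no conclusion is drawn from them. For lists, camera with a preset correlation gave 16 calls in the real split and 11 in the highest other. The mixed groups still differ in their share of hypoxia libraries. These calls thus do not show how many camera makes without an effect.

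Intron reads, which the comparisons in the report do not treat on their own, carried a signal of hypoxia. In uniquely mapped intron reads (13119 genes tested), edgeR's quasi-likelihood test called 2500 genes higher and 2100 lower under hypoxia than in the normoxia controls. In these reads, 15 of 17 measured genes of glycolysis and glucose uptake were higher, with a median log2 change of 2.16, and 28 of 31 HIF targets, with a median of 1.97. Across 11532 genes, exon and intron changes correlated with r = 0.804 and rho = 0.727, genes not being independent replicates. Reads counted as intron reads are not all from introns. The 13 mitochondrially encoded mRNAs, whose genes hold no introns, were measured in them too (8 lower, median -0.41). Such reads were 0.49% of the gene reads of MT-ND1 and 0.55% of those of MT-ND2. How far they enter the values of other genes was not tested.

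For 647 of 11568 genes, exon and intron reads changed by different amounts, the exon change lying above in 330 and below in 317. Reads of overlapping annotated genes are argued against as the whole source, since 42.3% of these genes overlap another gene (95% exact interval 38.5% to 46.3%), though as a part they stay open, with 25.2% among genes not called (odds ratio 2.18, Fisher's exact test p = 2.78e-20). HIF1A was one of the 647: its gene reads rose by 0.26 ± 0.036, its exon reads changed by 0.043 ± 0.037, and its intron reads rose by 2.45 ± 0.074, from 277.7 ± 12.5 to 1589.7 ± 31.7 reads (n = 3 per group), an exon change lower by 2.41 ± 0.076 than the intron change. The exon value argues against higher HIF1A mRNA as the source of the rise, and the annotation against another annotated gene, with 0 overlapping HIF1A. More unspliced HIF1A RNA and an unannotated transcript from either strand cannot be told apart with an intron change of 2.45 alone, because the libraries do not mark strand, and a biological response to hypoxia stays open as a hypothesis.

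MT-ND1, MT-ND2 and MT-CYB, singled out because they fell most of the 13 mitochondrial mRNAs, made up 12.5% ± 0.20 of mitochondrial mRNA reads under hypoxia against 20.9% ± 0.11 under normoxia (n = 3 per group, exact permutation p = 0.1, the smallest possible). Reads shared with nuclear copies in the build are argued against, since 0% of the reads of the 3 genes mapped to more than 1 place in any library. Reads of the mitochondrial rRNA gene at positions 70 to 1023 rose by 0.74 ± 0.13 (adjusted p = 0.0113) and those of the gene at 1091 to 2670 changed by -0.22 ± 0.083 (adjusted p = 0.0848, both by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Since RNA was selected with oligo-dT beads, the reads of these rRNA genes may reflect capture and do not show the amount of rRNA. A change of poly(A) tails that alters capture of single transcripts was not tested and stays open beside a change in the amount of these mRNAs under hypoxia.

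KRT14 rose by 2.35 ± 0.050, from 873.5 ± 12.2 to 4456 ± 369 CPM, in a line labelled as melanoma. Of the pigment cell markers, PMEL was at 7.88 ± 0.71 and 7.32 ± 0.14, S100B at 1.60 ± 0.13 and 1.51 ± 0.61 and MLANA at 0.56 ± 0.34 and 0.75 ± 0.40 CPM under hypoxia and normoxia, whereas SOX10 was at 65.6 ± 5.76 and 49.9 ± 2.92 CPM. The epithelial genes ITGB4 (573.2 ± 7.32 and 384.5 ± 12.6 CPM) and EPCAM (112.0 ± 4.91 and 124.2 ± 3.23 CPM) were above these 4 in both conditions. These are chosen genes. The pigment gene SLC45A2 was at 91.7 ± 4.34 and 65.9 ± 2.91 CPM. The epithelial genes LAMB3 (23.6 ± 0.96 and 11.6 ± 0.35 CPM) and COL17A1 (19.0 ± 2.24 and 16.4 ± 1.20 CPM) were below SOX10. CPM is not scaled by transcript length, so levels of different genes compare only roughly and do not settle the cell type. Reads that also match a keratin gene elsewhere in the build are argued against, since at most 0.00600% of KRT14 exon reads mapped to more than 1 place in any library. This share cannot detect reads of similar genes that are merged into the model or missing from the build. Reads of other genes inside the KRT14 model cannot be told apart from its own: the model spans 109520 bp with 36 exons and contains KRT9, and intron reads rose by 2.48 ± 0.045 against 2.31 ± 0.035 for exon-exon reads. A larger share of epithelial cells stays open as well. The 14 epithelial adhesion genes had a median change of 0.17, with 8 higher, among them LAMB3 by 1.02 and JUP by 0.66. The 4 lower ones included KRT10 (-0.45) and SFN (-0.43). Members of lower level moved both ways. LAMB3 went from 11.6 ± 0.35 to 23.6 ± 0.96 CPM, and SFN from 45.1 ± 3.67 to 33.5 ± 2.94 CPM. Normoxia levels such as 187.1 ± 8.69 CPM for CDH1 and 359.0 ± 4.93 CPM for DSP leave room for added cells to go unseen. A response of KRT14 itself to hypoxia stays open as a hypothesis.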

How the results depend on the processing

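Exon reads only and thinned counts were alternatives chosen after the data were seen, and all others were fixed before. Over 22 alternatives, genes called higher numbered between 2550 and 3874 and lower between 3074 and 4862, apart from the 1.5-fold null, which by its construction left 756 and 95. DESeq2 called 3359 and 3370, exon reads only 3281 and 3200, thinned counts 3732 and 3702, and leaving out 1 library 3416 to 3598 and 3361 to 3585. Library size only gave a median log2 change of -0.065 and 38.8% higher among calls, against 50.1%. Over all genes, deviations of libraries with equal replicate numbers were not positively correlated (-0.087, -0.013 and -0.031), and 0 of 6 libraries correlated best with their own number. The main test took no pairs because the labels state none, a choice fixed before. Whether equal numbers are pairs stays open, since some library measures described below ranked alike by number in both conditions. With replicate as a block 3769 genes were higher and 3793 lower. Over all genes, some calls of the main test reversed: 10 with log2(TPM + 1), 11 with log2(TPM + 0.1) and 8 from exon reads only. Calls shared with the same sign there numbered 5335, 5226 and 6072. Of the 57 named genes, 40 kept call and direction under every alternative and 0 reversed. The 1.5-fold null ended 16 calls, HIF1A lost its call on both TPM scales and from exon reads, and NGFR without hypoxia or normoxia replicate 1. Depth limits low genes most: the NTSR1 change rests on 4 normoxia reads, the FAM71F2 change on 6.

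Of the 21 lists, 4 kept their call under all 12 alternatives: glycolysis, HIF targets, collagen modification and serine metabolism, the last never called. With an estimated correlation 3 lists were called, and adjusted p rose past 0.05 for glycogen (0.101), nuclear (0.274) and mitochondrial respiratory chain (0.104), cholesterol (0.0727), fatty acid synthesis (0.157), pentose phosphate (0.274), unfolded protein (0.0727), mitosis (0.0727), DNA replication (0.181), ribosome biogenesis (0.0898), mesenchymal (0.0727), interferon (0.264) and other cell types (0.121). Fry, which asks only whether a list's genes move on balance one way and compares them with no other genes, called the TCA cycle (0.00478), fatty acid oxidation (0.00211) and immediate early genes (0.00183), and turned the melanocyte list to up without a call (0.428). Library size only called the TCA cycle (0.0312) and fatty acid oxidation (0.0454). With 1 library left out, called lists numbered 16 to 18, the TCA cycle ranged from 0.0441 (without normoxia replicate 3) to 0.117 and fatty acid oxidation from 0.0468 (without normoxia replicate 3) to 0.105. Pentose phosphate lost its call from exon reads only (0.0520). The cause of these list changes was not tested.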

Other observations

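The list of further NRF2 targets was fixed, and its test chosen, before its values were seen, while the first NRF2 list and the single long non-coding RNA gene were picked from values already seen.

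Several genes seen among the falls are known targets of NRF2, the transcription factor of the antioxidant response. The thioredoxin reductase TXNRD1 fell by 1.29, PIR by 1.33, the haem oxygenase HMOX1 by 1.22, and NQO1 and the glutathione synthesis enzyme GCLC by 0.67 each, and the 14 targets picked in this way, because they fell, had a median log2 change of -0.67. As a hypothesis, a shared fall of NRF2 target expression under hypoxia was tested on 24 targets not looked at before, 19 of them measured. Of these, 12 were lower, 3 higher and 4 not called, with a median of -0.27. The glutathione reductase GSR (-0.87 ± 0.044) and PTGR1 (-0.91 ± 0.032) fell most, while EPHX1 rose (0.89 ± 0.056). Camera with a preset correlation gave an unadjusted p = 0.00386 for a fall against other genes, and an unadjusted p = 0.141 with an estimated correlation. The criterion fixed before had named an adjusted p below 0.05, and no adjustment over lists was made here. The values go with a fall of part of these targets, but the call depends on the camera setting. NRF2 protein was not measured here.

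A single long non-coding RNA gene took 0.564%, 1.12% and 1.55% of gene reads in hypoxia replicates 1, 2 and 3 and 0.520%, 0.812% and 0.969% in normoxia replicates 1, 2 and 3. By this share, by the intron share (23.9%, 24.8% and 25.2% under hypoxia, 23.6%, 23.9% and 25.1% under normoxia) and by the share of the 10 genes with the most reads, the libraries ranked alike by replicate number in both conditions, and hypoxia was higher at each number. These measures share reads, and the labels tie the numbers to no batch or day. The 10 genes with the most reads took 7.10% ± 0.45 of gene reads under hypoxia and 6.12% ± 0.20 under normoxia (n = 3 per group, exact permutation p = 0.1, the smallest possible).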
